A study of Mus musculus with 24 samples.

How the data were processed

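Gene expression of 24 pools of mouse blastocysts was measured on Affymetrix Mouse Gene 1.0 ST arrays, with 1 array per pool. Per the labels' protocols, each pool held the lysate of 3 embryos of 1 sex from 1 mother, taken on day 3.5 after mating. RNA was amplified without purification from the lysate and labelled with biotin, using NuGEN kits. The high-fat cohort held 7 animals and the control cohort 14. Which mother and father each pool came from is not given in the sources used here. If these were all the animals, some of the 8 pools of obese mothers and of the 16 pools of lean mothers shared a mother, and the tests treat pools as independent.

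The deposited values are log2 intensities per probe set, made by the authors with RMA (background correction, normalization across arrays and summary of the probes of a set) and the affy package, per the submitters' processing notes. Versions, the probe set definition and the genome build are not given in the sources used here. The table held 35556 probe sets in 24 columns with 0 missing values, and 0 columns matched no sample. The arrays had nearly equal means but unequal standard deviations, so the values as deposited do not share 1 distribution. A wider spread on an array raises bright genes and lowers dim ones there. The number of arrays limits the precision.

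Probe sets were named through GEO's platform annotation. Of them 21789 had 1 gene symbol, 1621 had several and 12146 had none in that annotation, and probe sets with several or none were not named. Gene numbers of 21698 probe sets were found in a RefSeq gene table (GRCm38.p6), and 0 symbols changed through it. This table was used for names, chromosomes and for which gene lies inside which, and no coordinates are given because the files name no build. For 999 of the 19938 genes with more than 1 probe set, the set with the highest mean over all arrays was used. A gene was tested when at least 4 of the 24 arrays exceeded the median of all values, which left 13311 genes and removed 6627.

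Groups came from the labels. A linear model with a mean for each of the 6 groups was fitted to the log2 values of all 24 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates. Contrasts compared each obese parent with lean parents in each sex, male with female embryos for each kind of parents, the difference of these effects between the sexes, and obese mothers with obese fathers. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. Averages over both sexes or all parents were added after the data were seen. Genes named in the text are up to 15 called genes per direction with the largest fold change. Where fewer than 10 passed, they also come from the 10 higher and 10 lower with the smallest unadjusted p, leaving out names without information. Up to 4 members with the smallest unadjusted p of each list that passed are named, with Xist and the Y-linked genes in every case.

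Of 33 gene lists fixed before the data were examined, 32 had at least 5 tested members. They cover embryonic lineages, maternal and cleavage-stage transcripts, metabolism, stress responses, chromatin, translation, signalling, X-linked genes and markers of cells that could be carried over. The Y-linked list had 1 tested member and was not tested as a list. Lists were tested in limma with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, with adjusted p over the lists of a contrast. X-linked genes were compared with autosomal genes in the same way. Single values were compared with exact permutation tests (4 against 4 arrays, two-sided) or with 100000 permutations (12 against 12 arrays, and correlations over 24 arrays). Correlations across genes of contrasts with the same lean-parent arrays were set beside 1000 simulations of unchanged groups.

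The procedure was tested on simulated data for obese-father against lean-parent males, with 200 of 13311 genes changed. With the residual array profiles of the data, it recovered 4.25% of changes of 0.5 log2 units, 71.8% of changes of 1 and 92.0% of changes of 2, as means of 10 simulations. Alternatives fixed before the data were examined were no filter or a stricter filter on dim genes, all probe sets or the mean of a gene's probe sets, a trend and robust prior, array weights, the first residual principal component as a covariate, centring on medians or quantile normalization for the gene counts, fits with the contrast's groups alone, a threshold of 0.10 and leaving out each array. The array's standard deviation as a covariate, leaving out the 2 arrays of the widest spread, and both rescalings for the gene lists were added after the data were seen.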

Results

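Gene expression was measured in mouse blastocysts, the stage just before implantation, when an outer trophectoderm surrounds an inner cell mass and a fluid-filled cavity. Outbred NMRI mice had eaten a high-fat, high-calorie diet or a control diet for 9 weeks from the age of 3 weeks, and were mated at 12 weeks. Embryos had an obese mother and a lean father, a lean mother and an obese father, or lean parents, and were collected on day 3.5 after mating and sexed. Each array held a pool of 3 embryos of the same sex from 1 mother, and each of the 6 groups (3 kinds of parents, male and female) had 4 arrays, 24 in all. The labels do not say which mother and father each pool came from. They name a high-fat cohort of 7 animals and a control cohort of 14, and if these were all the animals, some of the 8 pools of obese mothers and some of the 16 pools of lean mothers shared a mother, within or between the sexes. The tests treat pools as independent, so p-values measure the spread between these pools and not between mothers. The study asked whether obesity of the mother or of the father changes the blastocyst transcriptome, and whether it does so differently in male and female embryos.

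All levels below are log2 values, and their precision is limited by the number of arrays. The median of the table was 2.56, and 13311 of 19938 genes were bright enough to be tested. Array means lay between 2.82 and 2.86, while the standard deviation of the values on an array (its signal spread) ranged from 1.27 in lean-parent male array 4 to 1.81 in obese-father female array 22. The first principal component, with 52.1% of the variance, followed this spread across the 24 arrays (Pearson r = 0.993, Spearman rho = 0.973, permutation p = 1e-05 for each, the smallest that 100000 permutations can give), and r was 0.987 without the 2 arrays farthest from the median spread. Correlations between arrays over all probe sets ran from 0.691 to 0.943, and their median within groups (0.917) was close to that between groups (0.914).

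Sex-linked transcripts were used as a check of the sex labels. Eif2s3y, a Y-linked gene for a subunit of a translation initiation factor, averaged 2.12 ± 0.52 (SD, n = 12) in male pools and 1.33 ± 0.18 (n = 12) in female pools, a difference of 0.79 (permutation test, two-sided, p = 1e-05, the smallest possible), and 10 of 12 male arrays exceeded every female array. Xist, the RNA that coats the inactive X chromosome, averaged 2.13 ± 0.28 (n = 12) in males and 2.74 ± 0.54 (n = 12) in females, a difference of -0.61 (permutation p = 0.00239), and 6 of 12 female arrays exceeded every male array. The X-linked homeobox gene Rhox1 was 0.37 higher in males (permutation p = 0.00191) and the Y-linked Uty 0.18 higher (permutation p = 0.0179). Rhox1 was added to the planned check of Xist and the Y-linked genes. It was also among the genes with the smallest p between the sexes with obese fathers, so it is no independent check. Uty was 0.40 higher in males with lean parents, 0.077 with obese mothers and 0.072 with obese fathers. The Y-linked Kdm5d, Sry, Uba1y, Usp9y, Zfy1 and Zfy2 differed by -0.09 to 0.07, with permutation p from 0.28 to 0.848. With Benjamini-Hochberg adjustment over these 10 genes, Eif2s3y (1e-04), Xist (0.00797), Rhox1 (0.00797) and Uty (0.0448) stayed under 0.05, whereas in limma over all genes none of them did. Uty stayed under 0.05 only with Rhox1 counted among the 10 genes, so it does not count as passing the planned check. Among offspring of obese fathers, Xist was 2.34 ± 0.33 in males and 2.42 ± 0.28 in females (n = 4 each; -0.08, exact permutation p = 0.743), against -0.85 between the sexes with lean parents (exact p = 0.0857) and -0.89 with obese mothers (exact p = 0.0571). The test of whether the obese-father effect on Xist differed between the sexes did not pass (0.78, SE 0.39, limma adjusted p = 0.654).

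**Figure D1:**
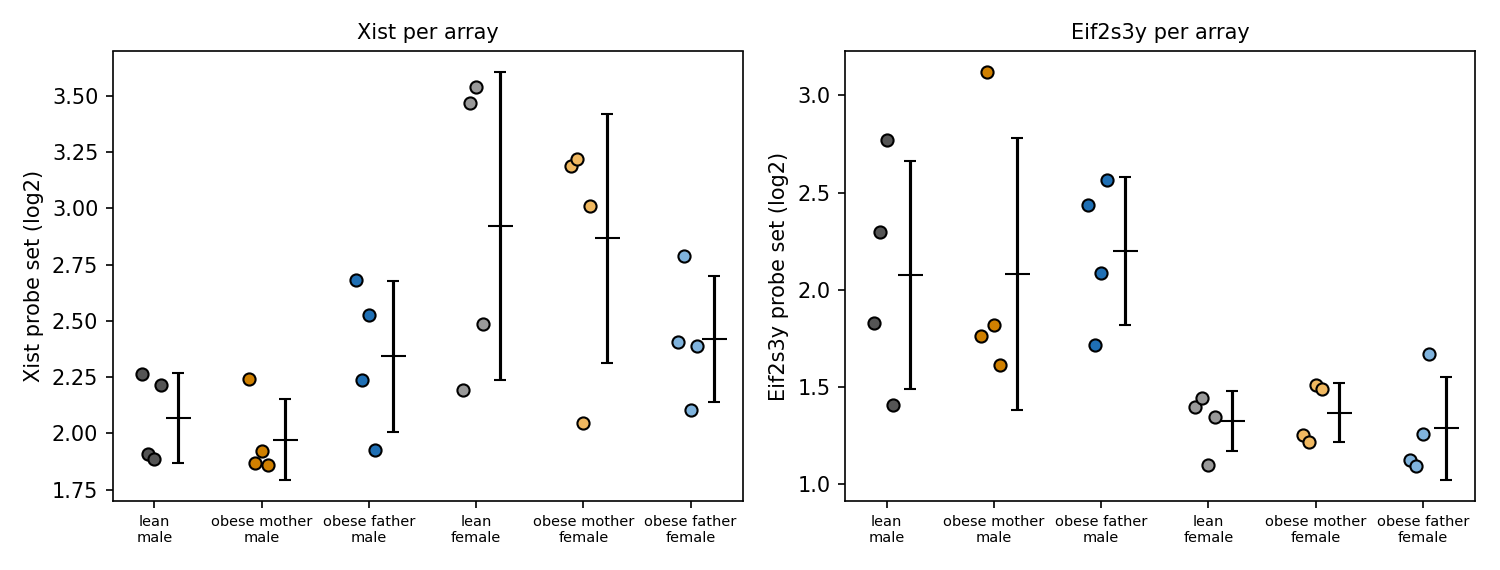
Levels of Xist (left) and Eif2s3y (right) on each of the 24 arrays, in log2 units, by kind of parents and sex. Points are arrays, and the bars beside them give the mean and SD of the 4 arrays of a group; male group means of Eif2s3y lay at 2.08 to 2.20 and female ones at 1.29 to 1.37.

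Male blastocysts of obese fathers were compared with males of lean parents. Snord47, a small nucleolar RNA gene that lies inside the non-coding host gene Gas5 and whose class guides the 2'-O-methylation of ribosomal RNA, was higher, at 3.79 ± 0.81 against 1.53 ± 0.46 (n = 4 each). The log2 fold change was 2.26 (SE 0.32), with a limma adjusted p of 0.00767, and all 4 obese-father male arrays (lowest 2.87) exceeded the other 20 arrays (highest 2.34). It was the 1 gene of 13311 past the threshold. Outside obese-father males its levels lay below the table median of 2.56, so it was bright enough to be tested through these 4 arrays alone, the size of the difference is uncertain, and the stricter filter removes it. The call ended without lean-parent male array 1 (log2 fold change 2.11) or obese-father male array 9 (2.17), and in a fit with these 2 groups alone. Gas5 itself stood at 10.30 ± 0.45 against 8.50 ± 1.42, a log2 fold change of 1.80 (SE 0.70) with an adjusted p of 0.316.

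Below the threshold, 1958 genes (14.7%) had an unadjusted p under 0.05 in this comparison, 572 of them higher and 1386 lower. With the array's signal spread as a covariate it was 956. Unchanged genes give on average a share of 0.05. Comparisons below without obese-father males had 1.41% to 3.37%, under that level, so their counts give no sign of change. The others, apart from averages, had 5.42% to 8.35%. For obese-father against lean-parent males, the fixed rule also names the 10 genes on each side with the smallest unadjusted p, given here as values and not as changes. On the higher side stood the zinc finger gene Zfp971, at 6.55 ± 0.36 against 2.79 ± 0.96, a log2 fold change of 3.76 that did not pass. In the fit with the array's signal spread as a covariate it was 2.21, with an adjusted p of 0.41 in that fit. The ribosome quality control ubiquitin ligase Ltn1 (1.89), the succinate dehydrogenase assembly factor Sdhaf1 (0.78), the coatomer subunit Copz1 (0.68) and the hair keratin-associated Krtap5-3 (1.44) also stood on the higher side without passing. The small RNA genes Mir680-1 (1.94, adjusted p = 0.198), Mir383 (1.41), Mir346 (0.81) and Snord8 (0.78) were among them, and apart from Mir680-1 these had an adjusted p of 0.316. On the lower side, Tlr2, a receptor of the innate immune system, stood at 2.47 ± 0.06 against 3.09 ± 0.13 (log2 fold change -0.62, adjusted p = 0.113). The others, at an adjusted p of 0.316, were the potassium channel gene Kcnj3 (-0.60), Ubqln5 (-0.74), the apolipoprotein gene Apom (-0.62), the glutathione transferase Gstk1 (-0.64), Parp8 (-0.60), the retromer subunit Vps26b (-0.73), Zfp658 (-0.74), the vomeronasal receptor gene Vmn1r58 (-1.14) and Inhba (-0.64), which encodes a subunit of activin.

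**Figure D2:**
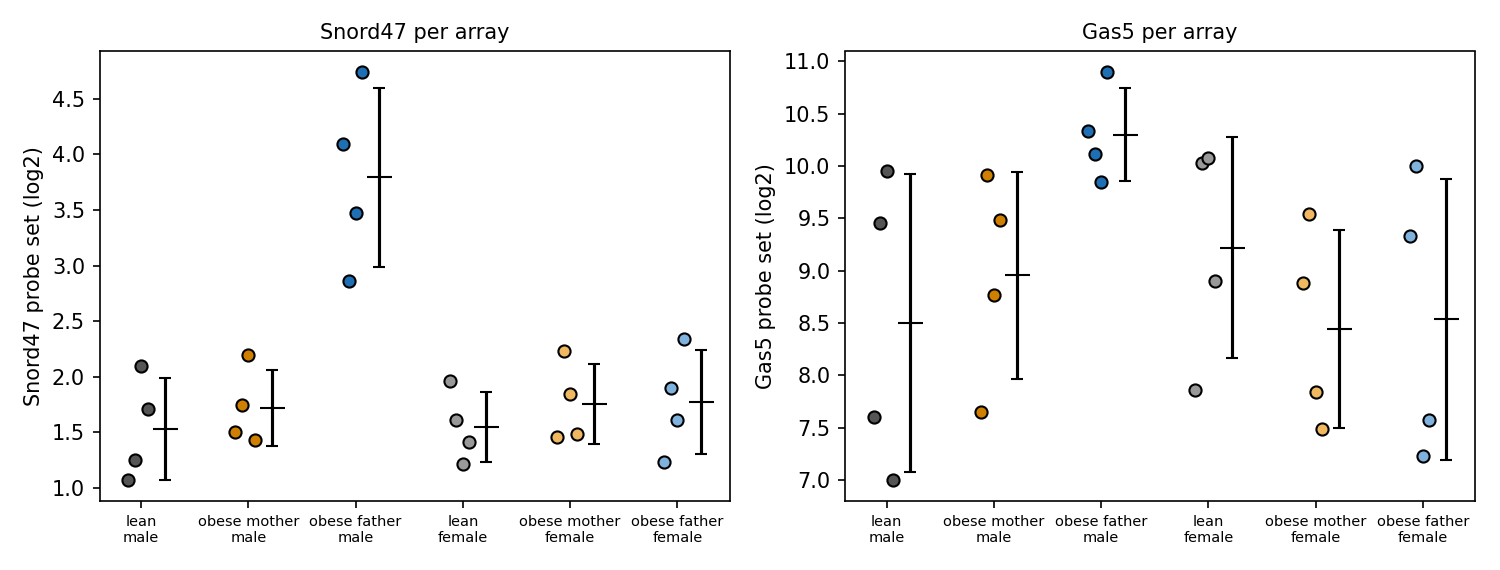
Levels of Snord47 (left) and of its host gene Gas5 (right) on each array, in log2 units, by group. Points are arrays, and bars give the mean and SD of 4 arrays; Snord47 lies between 2.87 and 4.74 in obese-father males and at or below 2.34 on the other 20 arrays, whereas Gas5 overlaps between groups.

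Of the 32 gene lists tested in the same comparison, 14 passed camera's competitive test with the preset correlation of 0.01, 13 higher and 1 lower than other genes. Cytosolic ribosomal protein genes lay highest, with a median log2 fold change of 1.37, and 53 of 53 members were above 0, 41 of them at an unadjusted p under 0.05. Among them were Rpl7a (1.29), Rps10 (1.47), Rps7 (1.84) and Rps15 (1.69). The adjusted p of the list was 2e-31, and it was 0.172 with an estimated correlation. Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, had a median of 0.84 with 67 of 73 members above 0 and 27 at an unadjusted p under 0.05, such as the complex III subunits Uqcrfs1 (1.27) and Uqcr10 (0.90), the complex I subunit Ndufs3 (1.31) and the cytochrome oxidase subunit Cox7a2 (1.38). Its adjusted p was 9.67e-22, and 0.172 with an estimated correlation. No member of these 2 lists passed, adjusted over all genes or adjusted over the list alone. The direction of both lists was the same after centring arrays on their medians (medians 1.45 and 0.93) and after a further quantile normalization (0.69 and 0.52). Centring moved the median over all tested genes from -0.11 to -0.03.

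Of other mitochondrial lists 3 passed. The tricarboxylic acid cycle had a median of 0.42 (19 of 26 above 0; Mdh1 1.11, Suclg1 0.83, Cs 1.03, Idh3b 0.63; adjusted p = 3.87e-05, or 0.199 with an estimated correlation), and with the array's signal spread as a covariate it turned lower without a call (-0.00365, adjusted p = 0.699). Mitochondrial biogenesis and dynamics had a median of 0.16 (22 of 30 above 0; the import channel Timm23 1.66, the chaperones Hspe1 1.85 and Hspd1 2.41, the protease Clpp 0.40; adjusted p = 4.43e-05, or 0.172 with an estimated correlation). Fatty acid oxidation had a median of 0.03 (14 of 26 above 0; Etfa 1.79, Acadm 1.66, Etfb 1.64, Acaa2 0.56; adjusted p = 0.0445, or 0.172 with an estimated correlation), and its call ended in 6 of 8 fits that left out 1 array, with arrays centred on their medians and with the signal spread as a covariate.

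Markers of the trophectoderm had a median log2 fold change of 0.28 with 23 of 30 above 0 (adjusted p = 2.88e-06, or 0.0865 with an estimated correlation). Adjusted over the list alone, 6 members passed, against 0 over all genes tested in limma, where 9 had an unadjusted p under 0.05. The members with the smallest p were the lysosomal precursor Psap (2.04), the actin-bundling Lcp1 (1.70), the tetraspanin Tspan8 (2.41) and the claudin Cldn4 (0.81). Genes of tight junctions and of ion and water transport into the blastocoel had a median of 0.22 (16 of 27 above 0; Pard6b 0.61, Cldn4 0.81, Marveld2 0.49, Aqp3 0.28; adjusted p = 0.000363, or 0.187 with an estimated correlation), and 1 passed when adjusted over the list alone. When 1 array was left out, the median of the tight junction list ran from 0.0297 to 0.275, and its call held. The fry test, which asks whether a list moves 1 way on balance, passed in this comparison for 1 list of the 32. That list was the p53 targets and apoptosis genes (median -0.13, adjusted p = 0.0424), which camera did not call. The median over all tested genes was -0.114, and fry, unlike camera, does not compare a list with other genes.

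The endoplasmic reticulum stress list had a median of 0.39 (18 of 27 above 0; Pdia6 1.16, Sec61b 1.53, Xbp1 0.39, Hsp90b1 1.93; adjusted p = 0.000175, or 0.172 with an estimated correlation). Ribosome biogenesis had 0.16 (28 of 43 above 0; Gar1 1.02, Fbl 0.83 and Gnl3 1.18, but the RNA polymerase I subunit Polr1e at -0.42; adjusted p = 0.000132, or 0.329 with an estimated correlation). Cell cycle genes had 0.14 (33 of 45 above 0; the cyclins Ccna2 1.23 and Ccnb2 0.96, Kif23 0.55, Aurka 0.83; adjusted p = 0.000132, or 0.36 with an estimated correlation), and with the array's signal spread as a covariate this list turned lower (median -0.20, adjusted p = 0.0155). The antioxidant list had 0.18 and was split, with the metallothionein Mt2 (1.44) and superoxide dismutase Sod1 above 0 and Gstm1 (-1.01) and catalase, Cat (-0.42), below (adjusted p = 0.00983, or 0.337 with an estimated correlation). Autophagy and lysosome genes had a median of 0.04 (19 of 36 above 0; Psap 2.04, Atp6v1h 0.98, Gla 1.01, Gabarapl2 1.73; adjusted p = 0.0126, or 0.249 with an estimated correlation). DNA methylation and chromatin genes had 0.15 (28 of 46 above 0; Hdac2 1.88 and Kdm5a 0.57 above, Prmt5 -0.51 and Sirt3 -0.33 below; adjusted p = 0.0217, or 0.336 with an estimated correlation). Leaving out 1 array ended the call of the antioxidant list in 3 of 8 fits and of each of the last 2 lists in 2 of 8. The calls of endoplasmic reticulum stress and ribosome biogenesis held in these fits. Their medians ran from 0.0781 to 0.623 and from 0.0476 to 0.273.

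Markers of cumulus and granulosa cells, which surround the oocyte, were the 1 list lower than other genes, with 15 of 15 members below 0 and a median of -0.28 (Inhba -0.64, Amh -0.53, Hsd3b1 -0.44, Nr5a1 -0.36; adjusted p = 0.0108, or 0.388 with an estimated correlation). The median over all tested genes was itself -0.114, and this list did not pass with the array's signal spread as a covariate. The other lists for foreign cells did not pass, with medians of -0.25 for blood and leukocytes (adjusted p = 0.0815), -0.21 for sperm transcripts (adjusted p = 0.107) and -0.19 for uterine and oviduct epithelium (adjusted p = 0.206). Lineage and maternal lists that did not pass were the inner cell mass and epiblast (0.03, adjusted p = 0.0719), primitive endoderm (-0.02, 0.365), oocyte-derived transcripts (-0.10, 0.668), cleavage-stage genome activation genes (0.30, 0.0966) and imprinted genes (-0.15, 0.668). Metabolic and stress lists that did not pass were glycolysis (0.03, 0.0796), fatty acid synthesis and lipid storage (-0.08, 0.704), cholesterol synthesis (-0.07, 0.18), insulin, IGF and mTOR signalling (-0.11, 0.924), the amino acid response (-0.09, 0.779), p53 targets (-0.13, 0.779), DNA repair (-0.02, 0.0926) and interferon and inflammation (-0.21, 0.238). X-linked germline and homeobox genes (0.25, 0.0587) and X-linked escape genes (-0.13, 0.779) completed the 18 lists without a call.

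These list values moved with the signal spread of the arrays, which was 1.56 ± 0.11 in obese-father males and 1.38 ± 0.12 in lean-parent males (n = 4 each, exact permutation p = 0.114). Over the 24 arrays, the mean of the ribosomal protein genes correlated with the spread (Pearson r = 0.946, Spearman rho = 0.977), as did that of oxidative phosphorylation (0.979 and 0.933) and of the trophectoderm markers (0.939 and 0.83), each with a permutation p of 1e-05, the smallest possible, and an adjusted p of 1e-05 over these 3 relations. Without the 2 arrays farthest from the median spread r was 0.965, 0.96 and 0.861. For deviations from the group means r was 0.942, 0.977 and 0.935. The spread is computed from the same values as these means, so a positive relation of bright lists is partly built in. The permutation p therefore does not test an independent link. With the spread as a covariate, chosen after the data were seen, 2 of the 32 lists passed, the ribosomal proteins (median 0.29, adjusted p = 4.91e-06) and the cell cycle in the lower direction, and 0 passed with an estimated correlation (smallest adjusted p = 0.68). Of the 14 lists 7 changed direction with this covariate, 1 of them, the cell cycle, past the threshold. In simulated groups with no change that kept the residual array profiles of the data, the preset test called the ribosomal list in 34 of 50 runs and oxidative phosphorylation in 36 of 50, and the test with an estimated correlation called neither. With the spread as a covariate the preset test still called the ribosomal list in 26 of 50 runs, oxidative phosphorylation in 12 and any list in 36, so the ribosomal call with this covariate does not separate a change from none.

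**Figure D3:**
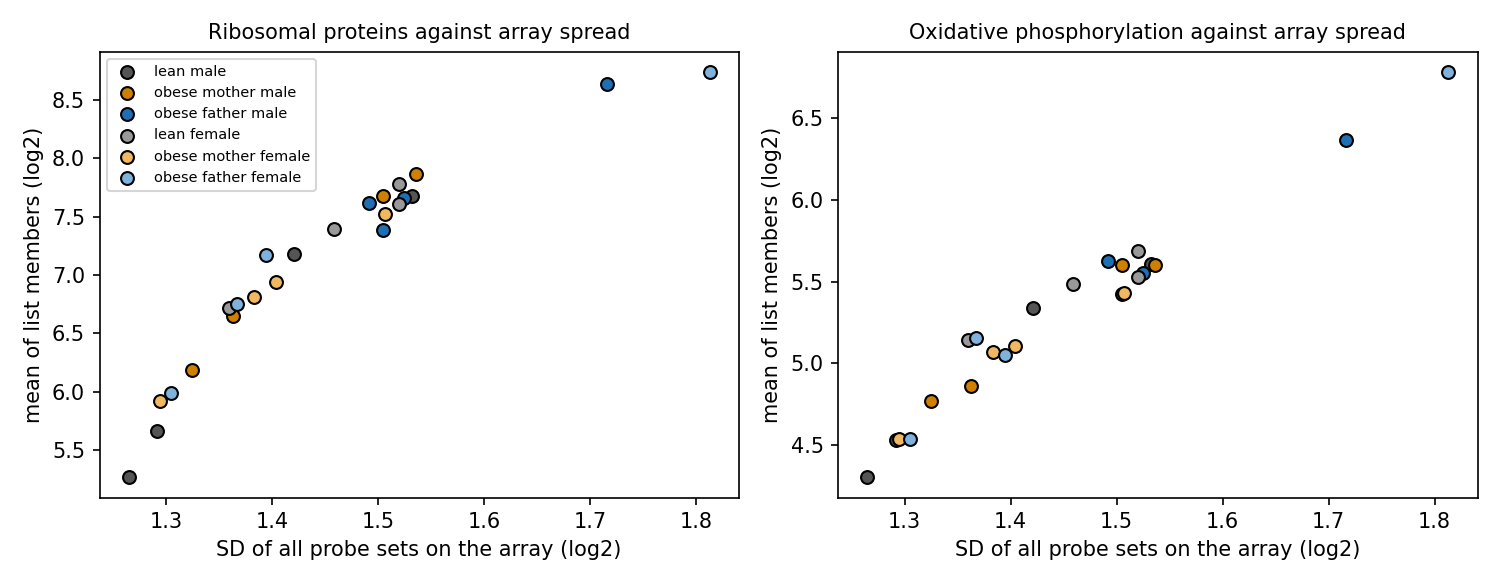
Mean level of the ribosomal protein genes (left) and of the oxidative phosphorylation genes (right) on each array against the standard deviation of all probe sets on that array, all in log2 units. Each point is 1 of the 24 arrays, coloured by group; the ribosomal mean runs from 5.27 at a spread of 1.27 to 8.74 at a spread of 1.81, and arrays of all groups lie along the same trend.

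Female blastocysts of obese fathers were compared with females of lean parents. No gene passed in limma, and 378 (2.84%) had an unadjusted p under 0.05. Snord47 stood at 1.77 ± 0.47 against 1.55 ± 0.32 (n = 4 each), a log2 fold change of 0.22. Among the values at the top of the ranking were the serine racemase gene Srr (0.69), the proteasome assembly factor Psmd9 (0.90), the RNA-binding protein gene Celf2 (0.54), the carnitine-acylcarnitine carrier Slc25a20 (0.55), the T-cell antigen Cd2 (0.44) and the cytokine receptor Csf3r (0.58). Among those at the bottom were the zinc transporter Slc39a5 (-0.54), Cracr2b (-0.51), Usf3 (-0.67), Fam53c (-0.61), Tmem256 (-0.64) and the tachykinin receptor Tacr2 (-0.47), all 12 with an adjusted p of 1.

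In this female comparison 3 lists passed with the preset correlation. DNA methylation and chromatin genes had a median of 0.13 with 32 of 46 above 0, among them Daxx (0.34), the histone demethylase Kdm4a (0.35), Dnmt3l (0.48) and the maintenance methyltransferase Dnmt1 (0.31), with an adjusted p of 0.0167. In camera's direction, which is relative to other genes, this list turned lower without a call with array weights (median 0.0056, adjusted p = 0.311). So it did without obese-father female array 22 (median -0.0194, adjusted p = 0.203). Cell cycle genes had 0.17 with 31 of 45 above 0, among them the replication genes Gins2 (0.31), Cdc6 (0.78) and Mcm6 (1.16) and the cyclin Ccne1 (0.32), with an adjusted p of 0.0363, but the list turned lower with array weights (-0.14, adjusted p = 0.012) and without obese-father male array 12 and female array 22 (-0.15, adjusted p = 0.00165). Ribosomal proteins had -0.22 with 46 of 53 below 0 (Rpl27a -0.75, Rps29 -0.65 and Rpl22 -0.55, but Rplp0 at 1.03; adjusted p = 0.0167), but 5 of 8 fits that left out 1 array ended this call, and without obese-father female array 24 the list turned higher (0.189, adjusted p = 0.216). With an estimated correlation the adjusted p of each was 0.898. Obese-father female array 22, of the widest spread, entered this comparison, and without it and obese-father male array 12 the number of lists was 10. It was 4 with the spread as a covariate, and 0 with this covariate and an estimated correlation (smallest adjusted p = 0.559).

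Male blastocysts of obese mothers were compared with males of lean parents. No gene passed in limma, and 226 had an unadjusted p under 0.05. The ribosomal protein genes had a median log2 fold change of 0.70 with 52 of 53 above 0, among them Rps10 (1.02), Rpl7a (0.82), Rps2 (1.15) and Rpl12 (0.44), with an adjusted p of 1.1e-15, or 0.972 with an estimated correlation. Oxidative phosphorylation had 0.20 with 56 of 73 above 0, among them Uqcrfs1 (0.81), Atp5l (0.93), Ndufa5 (0.78) and Uqcr10 (0.53), with an adjusted p of 4.58e-05, or 0.995 with an estimated correlation. The array spread was 1.43 ± 0.10 against 1.38 ± 0.12 (n = 4 each, exact permutation p = 0.486), and with it as a covariate the oxidative phosphorylation list did not pass (adjusted p = 0.666) and the ribosomal list did (adjusted p = 2.62e-08), but 0 lists passed with this covariate and an estimated correlation (smallest adjusted p = 0.701). From 1 to 8 lists passed when 1 array was left out. The call of oxidative phosphorylation ended in 4 of 8 such fits (medians from 0.0571 to 0.457). The ribosomal call held in them, with medians from 0.264 to 1.13. Genes near the smallest p were the palmitoyltransferase gene Zdhhc22 (0.67), Ciapin1 (0.62), a factor of cytosolic iron-sulfur protein assembly, Rlf (0.69), Stxbp6 (0.58) and Iftap (0.82) on the higher side. On the lower side stood Atxn7 (-0.48), Gstk1 (-0.51), Tlr2 (-0.38), C1d (-0.64), Vps26b (-0.57) and Tmed3 (-0.48), and all 11 had an adjusted p of 1.

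Female blastocysts of obese mothers were compared with females of lean parents. No gene passed in limma, and 291 had an unadjusted p under 0.05. Here the ribosomal protein genes had a median of -0.61 with 50 of 53 below 0, among them Rpl27a (-1.08), Rplp1 (-0.98), Rpl36 (-0.90) and Rps29 (-0.93). Oxidative phosphorylation had -0.41 with 60 of 73 below 0. Among its members were Ndufa6 (-0.94), Ndufs3 (-0.86) and Ndufs4 (-1.47), while Ndufa3 stood at 0.35. Each had an adjusted p of 2.14e-14, and of 0.651 with an estimated correlation. The array spread was 1.40 ± 0.09 against 1.46 ± 0.08 (n = 4 each, exact permutation p = 0.314), and with it as a covariate both lists passed (adjusted p = 0.000676 and 0.0012), but 0 lists with this covariate and an estimated correlation (smallest adjusted p = 0.739). Leaving out 1 array gave from 2 to 11 lists. Both calls held, with medians from -0.853 to -0.259 for ribosomal proteins and from -0.535 to -0.256 for oxidative phosphorylation. The autophagy and lysosome list had -0.07 with 22 of 36 below 0 (adjusted p = 0.0409, or 0.651 with an estimated correlation), and its call ended in 5 of 8 fits that left out 1 array. Of its members Map1lc3a, which encodes an autophagosome coat protein, passed when adjusted over the list alone (2.50 ± 0.25 against 3.25 ± 0.20, log2 fold change -0.74). Other values at the lower end were Vps51 (-0.45), Ccdc97 (-0.63), the nuclear receptor coactivator Ncoa3 (-0.47), the helicase Rtel1 (-0.53), Gna11 (-0.64), the mitochondrial import subunit Tomm6 (-0.74) and Bola3 (-0.60). At the upper end stood Cd2 (0.54), Rhpn1 (0.47), Cfap45 (0.46), Pramel19 (0.69), Gdap2 (0.76), Rdh9 (0.76) and the fatty acid hydroxylase Fa2h (0.46), these 14 with an adjusted p of 0.999.

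**Figure D4:**
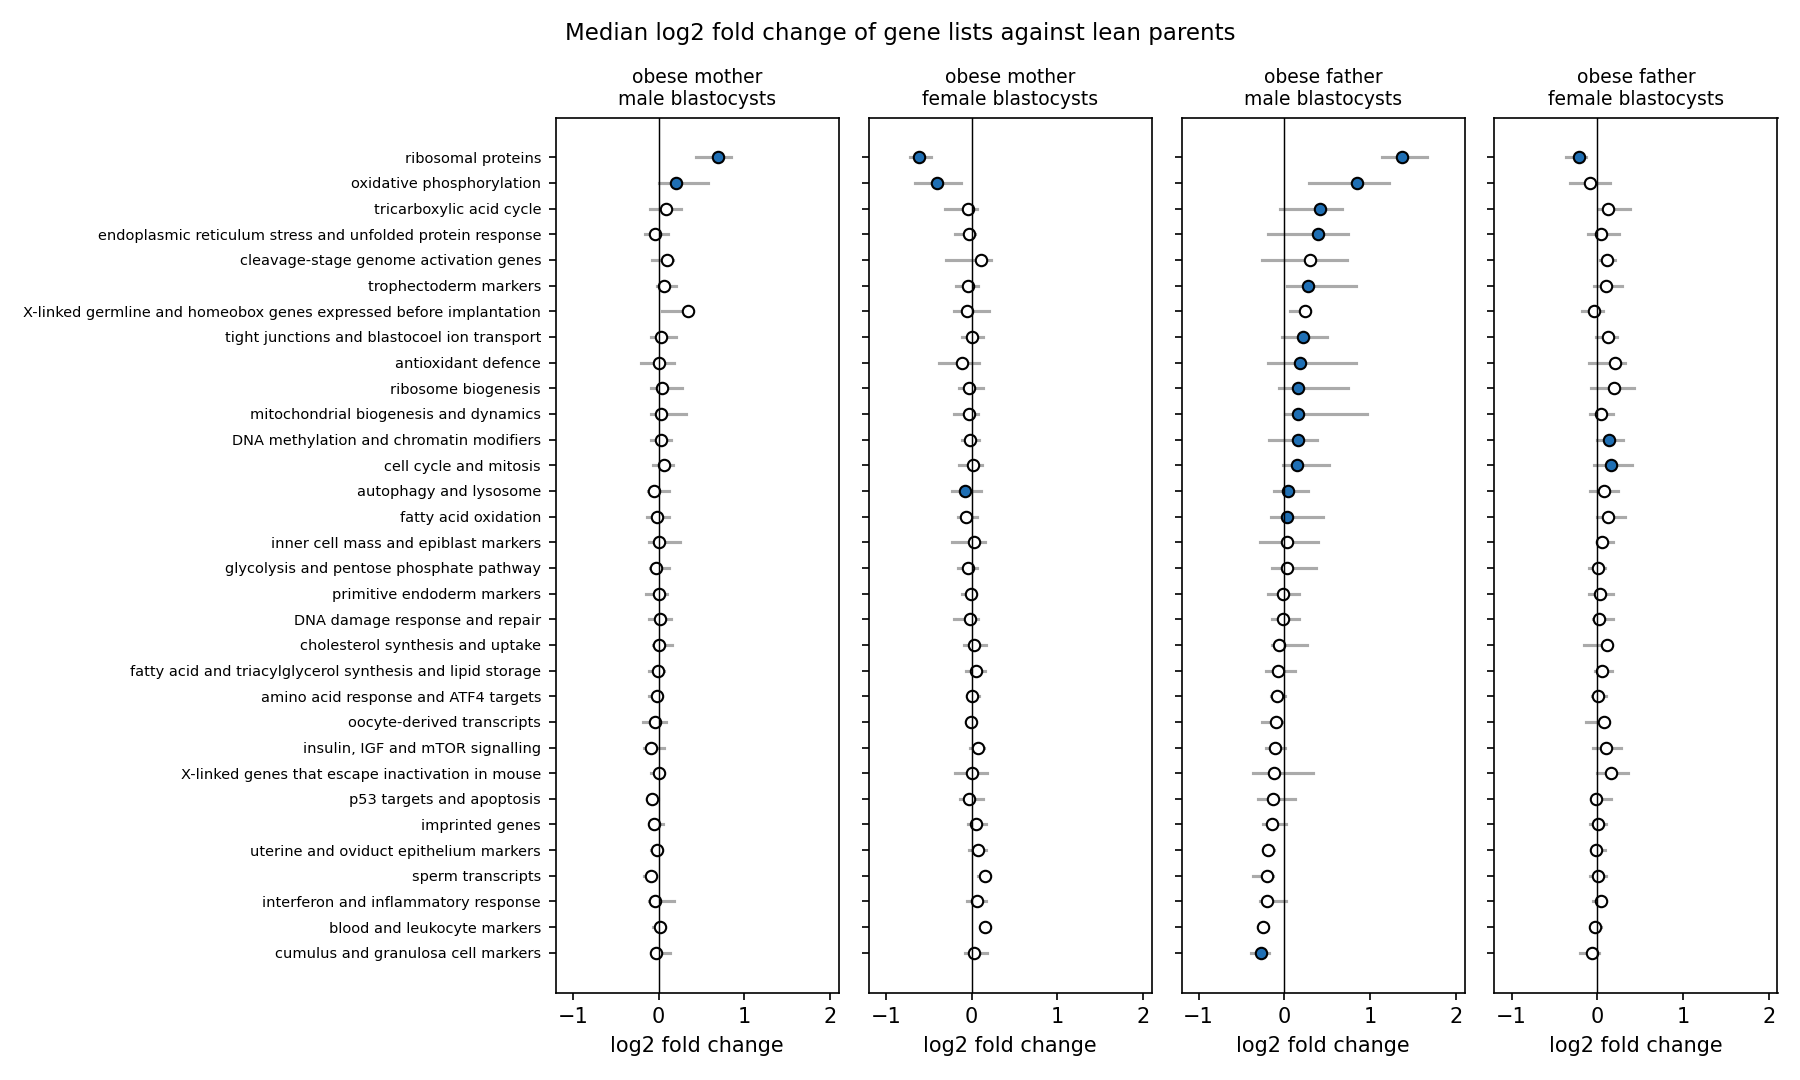
Median log2 fold change of the tested members of 32 gene lists in each comparison with lean parents, ordered by obese-father males. Points are medians, grey lines run between the quartiles of the members, and filled points are lists with a camera adjusted p under 0.05 at the preset correlation; no list passed with an estimated correlation.

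Male and female blastocysts were then compared within each kind of parents. With lean parents no gene passed in limma and 448 had an unadjusted p under 0.05. Ribosomal proteins (median -1.04, 52 of 53 lower in males; Rpl10 -1.49, Rpl12 -0.56, Rpl27a -1.16, Rps15 -1.39; adjusted p = 1.23e-27) stood lower in males. So did oxidative phosphorylation (-0.59, 58 of 73 lower in males; Uqcr10 -0.80, Atp5g3 -1.40, Ndufc1 -0.80, Ndufa1 -1.71; adjusted p = 6.62e-17). Each had an adjusted p of 0.448 with an estimated correlation. The array spread was 1.38 ± 0.12 in males and 1.46 ± 0.08 in females (n = 4 each, exact permutation p = 0.286). With it as a covariate 2 lists passed, or 0 with an estimated correlation as well (smallest adjusted p = 0.56), and leaving out 1 array gave from 2 to 13. In the same direction, 6 more lists passed, with adjusted p (estimated correlation in brackets) of 0.00516 for mitochondrial biogenesis (0.465), 0.0107 for the tricarboxylic acid cycle (0.612), 0.0274 for the cell cycle (0.816), trophectoderm (0.448) and X-linked germline and homeobox genes (0.34), and 0.0455 for autophagy (0.514). Each of these 6 calls ended in 3 to 5 of the 8 fits that left out 1 array. With the spread as a covariate the cell cycle (0.163), autophagy (0.0344) and the tricarboxylic acid cycle (0.0297) turned higher in males without a call. In the fits with 1 array left out the median ran from -0.101 to 0.0147 for the cell cycle and from -0.146 to 0.00322 for trophectoderm. It ran from -1.4 to -0.573 for ribosomal proteins and from -0.735 to -0.294 for oxidative phosphorylation, and both of these calls held. The X-linked list held Xist (-0.85), which passed when adjusted over the list alone. Single genes with the smallest p included Pramel19 (0.77), the mitochondrial cholesterol-binding protein Tspo (0.45) and the deoxyhypusine hydroxylase Dohh (0.64) on the male side and Tomm6 (-0.87), Dazap2 (-1.10), the nucleoporin Nup62 (-0.90) and Marcksl1 (-0.91) on the female side, with an adjusted p of 0.992.

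With obese mothers no gene passed in limma between the sexes and 188 had an unadjusted p under 0.05. Ribosomal proteins had a median of 0.34 with 46 of 53 higher in males (Rpl36 0.84, Rps29 0.77; adjusted p = 0.000732) and oxidative phosphorylation 0.18 with 49 of 73 higher (Cox7a2 0.83, Ndufb2 0.29; adjusted p = 0.0102), and both had an adjusted p of 0.965 with an estimated correlation. The array spread was 1.43 ± 0.10 in males and 1.40 ± 0.09 in females (n = 4 each, exact permutation p = 0.657). With it as a covariate 0 lists passed, and leaving out 1 array gave from 0 to 2, each of the 2 calls ending in 3 of 8 fits. In these fits the medians ran from 0.018 to 0.664 for ribosomal proteins and from 0.0277 to 0.274 for oxidative phosphorylation. Gene values at the male end were Ccdc97 (0.59), Gna11 (0.64), Map1lc3a (0.58) and the class II antigen gene H2-Ab1 (0.37), and at the female end Tmem198b (-0.38), the ubiquitin-conjugating enzyme Ube2t (-0.39), Xist (-0.89) and Gdap2 (-0.70), with an adjusted p of 1.

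With obese fathers Snord47 was higher in males than in females, at 3.79 ± 0.81 against 1.77 ± 0.47 (n = 4 each), a log2 fold change of 2.02 (SE 0.32) with an adjusted p of 0.0399. It was the 1 gene that passed, and 721 had an unadjusted p under 0.05. The call ended without obese-father female array 21 (log2 fold change 1.84), 22 (2.07) or 23 (1.97), without obese-father male array 9 (1.93), 11 (2.13) or 12 (1.71), with arrays centred on their medians (2.06), without the 2 arrays of the widest spread (1.75) and in a fit with these 2 groups alone (2.02). Values that did not pass were Rhox1 (0.73), Mir680-1 (1.74), Slc39a5 (0.54) and the lower Epb41l5 (-0.60) and Lmo1 (-0.43), each with an adjusted p of 0.415, and Rnaseh2a (-0.78, adjusted p = 0.46). Of the lists 5 passed with the preset correlation, ribosomal proteins (0.71, 50 of 53 higher in males, adjusted p = 2.14e-15), oxidative phosphorylation (0.33, 54 of 73, 1.31e-08), endoplasmic reticulum stress (0.18, 17 of 27, 0.00693), trophectoderm (0.17, 18 of 30, 0.02) and mitochondrial biogenesis (0.07, 18 of 30, 0.0463). With an estimated correlation their adjusted p were 0.799, 0.84, 0.638, 0.638 and 0.84. The array spread was 1.56 ± 0.11 in males and 1.47 ± 0.23 in females (n = 4 each, exact permutation p = 0.457). With it as a covariate 3 lists passed and mitochondrial biogenesis turned lower without a call (-0.035, adjusted p = 0.963), and 0 passed with this covariate and an estimated correlation (smallest adjusted p = 0.269). From 1 to 14 lists passed when 1 array was left out. The calls of trophectoderm and mitochondrial biogenesis each ended in 5 of 8 such fits, of endoplasmic reticulum stress in 3 and of oxidative phosphorylation in 1. The median ran from 0.258 to 1.29 for ribosomal proteins and from 0.0401 to 0.901 for oxidative phosphorylation. The 366 X-linked genes did not shift against the 12890 autosomal ones between the sexes in camera, with an adjusted p of 0.429.

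Whether the effect of a parent's obesity differed between male and female embryos was tested as an interaction. For obese fathers no gene passed in limma and 1003 had an unadjusted p under 0.05. Mir680-1 (2.71, SE 0.54), Snord47 (2.04, SE 0.46), Krtap5-3 (2.33), Mir692-1 (2.83), the superoxide dismutase Sod1 (2.47) and Ndufs3 (1.83) had a male minus female difference of effects above 0. Kank1 (-0.80), Celf2 (-0.83), Tlr2 (-0.62) and the interferon gene Ifng (-0.71) had a difference below 0, which does not say in which sex the effect lies. Each of these 10 had an adjusted p of 0.654. So the effect on Snord47, past the threshold in males and not in females, was not shown to differ between them. Of the lists 6 passed with the preset correlation, led by ribosomal proteins (median difference 1.63, 53 of 53 above 0, adjusted p = 1.06e-32, or 0.321 with an estimated correlation) and oxidative phosphorylation (0.98, 60 of 73 above 0, adjusted p = 5.33e-19, or 0.388 with an estimated correlation). With the array spread as a covariate 4 lists passed, or 0 with an estimated correlation as well (smallest adjusted p = 0.42), and leaving out 1 array gave from 4 to 13. For obese mothers no gene passed in limma and 344 had an unadjusted p under 0.05. The difference of effects was above 0 for Ccdc97 (0.91), Tomm6 (1.16) and Dazap2 (1.54), and below 0 for the mitochondrial ribosome gene Mrpl16 (-0.79) and the clock gene Cry2 (-0.61), at an adjusted p of 1. Here 3 lists passed, ribosomal proteins (1.33, 52 of 53 above 0, adjusted p = 2.91e-26), oxidative phosphorylation (0.55, 62 of 73, 2.61e-16) and trophectoderm (0.14, 21 of 30, 0.0178), each with an adjusted p of 0.488 with an estimated correlation. With the array spread as a covariate 4 lists passed, or 0 with an estimated correlation as well (smallest adjusted p = 0.57), and leaving out 1 array gave from 2 to 11.

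Across genes, which are not independent replicates, the male and female log2 fold changes had r = -0.26 for obese mothers and 0.07 for obese fathers. Of 100 regroupings of the arrays, 16 gave a value as low as that for mothers, and 52 one as high as that for fathers. Without obese-father female array 22, r for fathers was -0.627. The obese-mother and obese-father fold changes share the lean-parent arrays, and had r = 0.574 in males and 0.37 in females. Simulated unchanged groups with a shared control group gave a mean r of 0.485, with values from -0.229 to 0.899 after trimming both tails. This was set beside the male value, and a repeat of the simulation, set beside the female value, gave 0.468. Both drew residual profiles from the arrays of all groups and both sexes, so neither is specific to a sex or to the lean-parent arrays. Without obese-father female array 22, the observed r in females was 0.687. The covariance was 0.05 in males against 0.0433 simulated, and 0.018 in females against 0.0405. With the lean-parent arrays split between the 2 comparisons, the mean r of 3 splits was 0.158 in males (from -0.507 to 0.442) and -0.0684 in females (from -0.291 to 0.0889), so the sign was not settled.

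Set directly against each other, male blastocysts of obese mothers had less Snord47 than those of obese fathers (1.72 ± 0.34 against 3.79 ± 0.81, n = 4 each; log2 fold change -2.08, SE 0.32, adjusted p = 0.0279). It was the 1 gene that passed, and 1112 had an unadjusted p under 0.05. The call ended without obese-father male array 9 (-1.98), 11 (-2.18) or 12 (-1.76), without obese-mother male array 5 (-2.004), 6 (-2.08) or 8 (-1.98), with the array spread as a covariate (-1.98, adjusted p = 0.0765), without the 2 arrays of the widest spread (-1.76), with all probe sets, and with these 2 groups alone. Values that did not pass included Inhba (0.80) and Sdhaf1 (-0.91), each with an adjusted p of 0.271. Mecr, which acts in mitochondrial fatty acid synthesis, stood at 0.75 (adjusted p = 0.315) and the replication gene Gins1 at -2.27 (adjusted p = 0.573). In females no gene passed in limma and 433 had an unadjusted p under 0.05, with thymidylate synthase, Tyms, at 0.70 and Rnaseh2a at -0.66 (adjusted p = 0.975). Averaged over both sexes, limma called no gene for obese mothers (202 at an unadjusted p under 0.05), for obese fathers (986) or, averaged over all parents, between the sexes (289).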

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

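The tests with the array's signal spread as a covariate for the ribosomal and oxidative phosphorylation lists and for the genes called with a residual component, and the fit of Snord47 with Gas5 as a covariate, were chosen after the result was seen.

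Obese-father male array 12 stood apart from its group in signal spread (1.716), obese-father female array 22 in the mean of the trophectoderm markers (4.921), obese-mother male array 5 in Xist (2.24) and obese-mother male array 6 in Eif2s3y (3.121). Dixon's test was run on 48 pairs of a group and a measure, and chance alone marks about 1 in 20 groups.

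The obese-mother effect differed between the sexes by camera's preset test for ribosomal proteins (adjusted p = 2.91e-26), oxidative phosphorylation (adjusted p = 2.61e-16) and trophectoderm markers (adjusted p = 0.0178), each with an adjusted p of 0.488 with an estimated correlation. The obese-father effect differed for ribosomal proteins (adjusted p = 1.06e-32, or 0.321 with an estimated correlation), oxidative phosphorylation (adjusted p = 5.33e-19, or 0.388), mitochondrial biogenesis (adjusted p = 0.00135, or 0.388), trophectoderm markers (adjusted p = 0.0016, or 0.321), endoplasmic reticulum stress (adjusted p = 0.00543, or 0.388) and the tricarboxylic acid cycle (adjusted p = 0.029, or 0.678). List means followed the signal spread of the arrays, whose own sex difference of the effect was 0.122 for obese mothers and 0.176 for obese fathers. With the spread as a covariate 4 lists passed for each, or 0 with an estimated correlation as well, and the tricarboxylic acid cycle turned lower without a call (-0.19, adjusted p = 0.209). Leaving out 1 array changed the call of that list, and of trophectoderm markers for obese mothers, in 7 of 16 fits each. Among 7806 probe sets without a single gene symbol, limma called 2 between males and females of obese fathers, 1 higher and 1 lower (-1.67), with 732 at an unadjusted p under 0.05.

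Ribosomal protein and oxidative phosphorylation genes were higher in males of obese fathers than in males of lean parents by camera's preset test but not with an estimated correlation (adjusted p = 0.172 for each), and both list means followed the signal spread of the arrays. With that spread as a covariate the oxidative phosphorylation list no longer passed (median 0.84 before and 0.06 after, adjusted p = 0.458), as a difference in spread would give. The covariate cannot decide this, because the list mean followed the spread within groups (r = 0.977), so a shift of the list would be removed too. After a further quantile normalization, which evens out the spread, the medians of both lists were still above 0. The ribosomal list still passed (median 1.37 before and 0.29 after, adjusted p = 4.91e-06), but not with an estimated correlation (adjusted p = 0.68), and the preset test with this covariate called it in 26 of 50 simulations without a change, so for this list the spread and a change of its own cannot be told apart. Members of a list moving together between arrays of a group cannot be told apart from a change of the list: the exact permutation p of the list means per array (0.314 for ribosomal proteins and 0.629 for oxidative phosphorylation) came after regression on the spread, which removes that joint movement. The spread itself may come from amplification or from the embryos, and an effect of paternal obesity stays open and untested.

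Snord47 was higher in males of obese fathers. The other 30 Snord genes had a median log2 fold change of 0.0803 (SE 0.131, from -1.552 to 1.252), which argues against a shift of all such probe sets. These 30 were taken whether or not they were bright enough to be tested, and a shift may not show in dim ones. With the signal spread as a covariate the call of Snord47 held (2.12, adjusted p = 0.0271), which argues against the spread as the whole cause. The bound written for a single deviating array, that the call holds without each array, was not met, since it ended without lean-parent male array 1 (2.11) or obese-father male array 9 (2.17), but the log2 fold change never went below 1.947 and all 4 obese-father male arrays exceeded the other 20, so no single array carries it. A change of the host gene cannot be told apart: Gas5 stood 1.8 higher (adjusted p = 0.316), past the bound written for it, or 0.57 (SE 0.445, adjusted p = 0.834) with the signal spread as a covariate, whereas with Gas5 as a covariate Snord47 went from 2.26 (SE 0.324) to 2.19 (SE 0.372), its adjusted p of 0.103 coming with the larger error, and 5 arrays of other groups had Gas5 as high with Snord47 at or below 2.09. An effect of paternal obesity is a hypothesis that remains open.

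With the first residual component as a covariate, 1901 genes passed between males of obese fathers and of lean parents, against 1 without it. With the signal spread as a covariate, which also adjusts the group means, 2 genes passed, as a difference in spread between the groups would give. Of 35 splits of the 8 arrays with the component recomputed, 3 gave as many genes, the highest other 1991, so chance cannot be excluded. The 1901 genes may therefore reflect the spread of the arrays, and an effect of paternal obesity on them was not separated from it.

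Counts were repeated over 35 splits of the 8 arrays of a comparison, or 100 regroupings for the sex differences and averages, the real one included. In 2 comparisons, males of obese fathers against lean parents and males of obese mothers against obese fathers, 1 gene passed in the real split. The highest other split gave 0, so 1 of 35 splits gave as many. Chance is not excluded by this, since that is the smallest share 35 splits can give and is not adjusted for the number of comparisons. It also rests on 1 gene, Snord47, which was bright enough to be tested through the same 4 obese-father male arrays alone. The exact permutation test of Snord47 against lean-parent males had p = 0.0286, the smallest that 4 against 4 arrays can give, and an adjusted p of 0.1 over 7 comparisons. It uses the same splits, so it adds nothing to the count of splits. Between males and females of obese fathers, 6 of 35 splits gave at least the real 1 gene, the highest other 670. Chance cannot be excluded there, and 670 genes point to a structure of the samples, since that split had the largest difference in mean signal spread of the 35 (0.25, against 0.0892 in the real one). In the other comparisons the real count was 0, which 35 of 35 splits reach by construction, so the splits test nothing there. The highest other was 16 for obese mothers in males, 1 for obese fathers in females, 1 between obese mothers and fathers in females, and 0 for obese mothers in females and between the sexes with lean parents or obese mothers. By construction, 100 of 100 regroupings also reached the real 0 for the sex difference of the obese-mother effect (highest other 817, again in the regrouping with the largest difference in spread, 0.328) and of the obese-father effect (12). The same held for the averaged sexes (0), obese mothers (1) and obese fathers (0).

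For counts of lists at the preset correlation chance could not be excluded in any comparison. As many lists as in the real split came from 9 of 35 splits for obese fathers in males (14 real, 18 in the highest other) and 32 for obese fathers in females (3 and 17). For obese mothers it was 22 of 35 in males (2 and 17) and 17 in females (3 and 13). Between the sexes it was 13 of 35 with lean parents (8 and 16), 24 with obese mothers (2 and 17) and 25 with obese fathers (5 and 18). Of 100 regroupings, 50 reached the 3 lists of the obese-mother sex difference (highest other 16) and 56 the 6 lists of the obese-father one (18).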

How the results depend on the processing

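The array's signal spread as a covariate, the fits without the 2 arrays of the widest spread, and the list tests after rescaling were chosen after the data were seen. Of the values that answer a comparison, 401 were the same under an alternative and 117 moved. For named genes 1618 were the same, 22 lost and 22 gained a call, and 0 changed direction with a call. Genes called in neither fit count as the same here, and all 22 losses were of Snord47, the only gene called. For gene lists called at the preset correlation 646 were the same, 143 lost the call and 19 changed direction. Except where stated, the cause was not tested. No paired analysis was possible because each array has its own number from 1 to 24. How far signals lie above background was not measured, and dim genes, including most Y-linked ones, are limited by it.

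For obese fathers against lean parents in males, 1 gene passed, and 0 with the stricter filter or with these groups alone, where the spread rests on fewer arrays. It was 2 with array weights, 2 with the signal spread as a covariate and 1901 (759 higher, 1142 lower) with the residual component. Between males and females of obese fathers, 1 gene became 0 with the stricter filter, with median centring and with these groups alone, 3 with all probe sets, 21 with the residual component and 4 with the signal spread. Between obese mothers and fathers in males, 1 gene became 0 with the stricter filter, all probe sets, the signal spread, without the 2 widest arrays and with these groups alone, 2 with array weights and 601 with the residual component. Where limma called 0 genes, the residual component gave 2 for obese mothers in males, 2 for obese fathers in females, 11 between the sexes with lean parents, 1 between obese mothers and fathers in females, and 9 and 350 for the sex difference of the obese-mother and obese-father effects. The signal spread gave 2 for the latter.

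With an estimated correlation 0 lists passed in each of the 9 comparisons, and with fry 1 for obese fathers in males and 0 in the other 8. With array weights the lists were 5 for obese mothers in females, 1 and 11 between the sexes with obese mothers and obese fathers, and 7 and 14 for the sex differences of the obese-mother and obese-father effects. The residual component gave 5 for the sex difference of the obese-mother effect, and the mean of a gene's probe sets gave 1 for obese fathers in females. Between the sexes, median centring gave 5 lists with lean parents and 1 with obese mothers, and quantile normalization 4 and 0. With the signal spread there were 1 and 2 for obese mothers in males and females, 2 and 4 for obese fathers in males and females, 2, 0 and 3 between the sexes with lean parents, obese mothers and obese fathers, and 4 for each sex difference, but 0 in every comparison with this covariate and an estimated correlation. Without the 2 widest arrays there were 10 for obese fathers in females, 11 between the sexes with obese fathers and 13 for the sex difference of the obese-father effect.

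Directions of lists changed as follows, by median log2 fold change. With the signal spread as a covariate, for obese fathers in males, the cell cycle list turned lower past the threshold (-0.198, adjusted p = 0.0155). Without a call, antioxidant defence (-0.0404), autophagy (-0.115), DNA methylation and chromatin (-0.0962), ribosome biogenesis (-0.11), tight junctions (-0.0373) and the tricarboxylic acid cycle (-0.00365) turned in the same fit. So did autophagy (0.0344), the cell cycle (0.163) and the tricarboxylic acid cycle (0.0297) between the sexes with lean parents, mitochondrial biogenesis (-0.035) between the sexes with obese fathers, and the tricarboxylic acid cycle (-0.19) for the sex difference of the obese-father effect. For obese fathers in females, the cell cycle list turned lower past the threshold with array weights (-0.137, adjusted p = 0.012) and without the 2 widest arrays (-0.15, adjusted p = 0.00165), and DNA methylation and chromatin turned without a call (0.0056 and -0.0194, camera's direction lower). Leaving out 1 array there, the cell cycle ran from -0.15 without obese-father array 22 (lower, adjusted p = 0.00264) to 0.281 without array 24, DNA methylation and chromatin from -0.0194 to 0.265 and ribosomal proteins from -0.778 to 0.189, without the same 2 arrays.

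Leaving out each array in turn gave 0 to 2 genes for obese fathers in males, with 0 without lean-parent male array 1 or obese-father male array 9 and 2 without lean-parent male array 2 or 3. It gave 0 to 1 for obese fathers in females and between obese mothers and fathers in females, with 1 without obese-father female array 23. Between the sexes with obese fathers it gave 0 to 1, with 0 without female array 21 or male array 9, 11 or 12. Without female array 22 or 23 the 1 gene was not Snord47, and without array 23 it was lower in males. Between obese mothers and fathers in males it gave 0 to 2, with 0 without obese-father array 9, 11 or 12 or obese-mother array 5, 6 or 8, and 2 without obese-father array 10. Other gene counts stayed at 0.

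Lists in these fits ran from 10 to 17 for obese fathers in males. They ran from 0 to 10 for obese fathers in females (0 without lean-parent array 16, 10 without obese-father array 22, 6 to 8 without lean-parent array 14 or obese-father array 21, 23 or 24). For obese mothers they ran from 1 to 8 in males (8 without lean-parent array 3, 7 and 4 without obese-mother array 5 and 7, and 1 without lean-parent array 1 or 4 or obese-mother array 6 or 8) and from 2 to 11 in females (11 without obese-mother array 18, 6 without lean-parent array 13). Between the sexes they ran from 2 to 13 with lean parents (13 without male array 3, 2 without male array 1 or female array 14, 3 and 4 without male array 4 and female array 15), from 0 to 2 with obese mothers (0 without female array 19 or male array 6 or 8) and from 1 to 14 with obese fathers (14 without female array 22, 1 without female array 24, 2 without female array 23 or male array 12, 3 without female array 21). For the sex difference of the obese-mother effect they ran from 2 to 11 (11 without lean-parent male array 3, 9 without obese-mother female array 18, 6 to 7 without lean-parent female array 13 or obese-mother male array 5 or 7), and of the obese-father effect from 4 to 13 (13 without obese-father female array 22, 12 without lean-parent male array 3, 11 without lean-parent female array 13).

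Correlations across genes in these fits ran from 0.306 to 0.79 between obese-mother and obese-father effects in males and from 0.081 to 0.687 in females (the highest without obese-father female array 22). Between male and female effects they ran from -0.41 to 0.00203 for obese mothers and from -0.627 to 0.389 for obese fathers (the lowest without obese-father female array 22).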

Other observations

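The list of transcripts with a 5' terminal oligopyrimidine tract and its tests were chosen after the values of Gas5 and of the ribosomal protein genes were seen, from background knowledge.

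Gas5 and the ribosomal protein genes belong to the transcripts that begin with an oligopyrimidine tract, whose translation is regulated by growth signals, and a shift of this class may be a hypothesis for their joint position in males of obese fathers. Of 31 other such genes, 20 were tested, and their median log2 fold change of 0.94 lay at percentile 98.6 of 10000 random lists matched on mean level (median of these 0.24). The random lists were drawn gene by gene. They do not keep any joint movement of such genes between arrays, so the percentile may be too high. Members of the class included Naca (1.96, adjusted p = 0.316), Tpt1 (1.91, adjusted p = 0.316) and Eef2 (1.23, adjusted p = 0.338), and none passed. With the signal spread as a covariate, fitted over all 24 arrays, the median was -0.14, at percentile 0.49, so a higher position of the class is not shown apart from the spread. The class and the spread cannot be told apart here, because the covariate also removes any shift of the class that goes with the spread.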
